A study of Rattus norvegicus with 10 samples.

How the data were processed

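Islets of adult male Wistar rats were profiled on the 1-colour Affymetrix GeneChip Rat Genome 230 2.0, with 5 arrays for the standard chow and 5 for the cafeteria diet. Per the labels' protocols, the 10 arrays carried independent samples, islets were freed by collagenase, separated on a density gradient and picked by hand, and total RNA was turned into biotinylated cRNA. The deposited values are linear intensity values, and the submitters' processing notes name MAS5 without a version. MAS5 is Affymetrix's summary of perfect match and mismatch probes, which scales each array to a common mean. In the deposited table the mean signal after trimming 2% at each end lay between 500.1 and 500.2 on every array, so the arrays had already been scaled to the same level. The table held 31099 probesets, of which 57 were control probesets, and it gave no detection calls. A summary of this kind adds noise to dim probesets, and equal trimmed means hide any change in total RNA per cell.

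The arrays were grouped by their titles. In all 10 samples the title, source name and description (3 fields) name one diet and the diet characteristic (1 field) names the opposite. The grouping follows the 3 fields. If the diet characteristic were right, every sign reported here would turn, while the sizes and p-values would stay as they are. No measured value was used to choose between them.

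Gene symbols came from the platform annotation supplied with the table. Of the probesets, 20826 had 1 gene symbol, 436 had several and were not named, and 9780 had none there. The symbols covered 14217 genes. The entrez ID of 20758 of the probesets with 1 symbol was found in the RefSeq gene table of assembly GRCr8, and none of their symbols needed updating. Neither the array table nor its annotation named a genome build, so no coordinates are given. Probesets without a symbol in that annotation were tested and counted with the others, but not named or placed in gene lists.

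Signals were transformed as log2(value + 14.15), where the pseudocount is the 10th percentile of all values, so a fold change is on that scale and understates the change of dim genes. Probesets with a mean log2 value above the 40th percentile of the 31042 non-control probesets were tested, which left 18625 probesets: 14038 with 1 symbol, of 10301 genes, and 4587 with several or none. No further normalization was applied. Each probeset was tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) for cafeteria diet against standard diet, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The residual degrees of freedom were 8 and the prior added 3.11. On simulated data with the real means and residual spread and 200 of 18625 probesets changed, this test found 30 of 67 changes of 0.5 on the log2 scale, 57 of 67 changes of 1 and 64 of 66 changes of 2, with 6 false calls. The simulation drew probesets independently of each other. It held all sizes of change at once, and the many large changes ease the adjusted threshold for the rest. With fewer true changes a smaller share would be found, so these counts do not show what a lack of calls excludes.

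For the cafeteria diet against the standard diet, 26 gene lists (pathways, islet genes and markers of other cell types) were tested with limma's camera at its preset correlation of 0.01 between genes, using the brightest probeset of each gene and lists with at least 5 members. That left 25 lists, and each was tested again with an estimated correlation. In a simulation over 10301 genes in which 1 list was raised, camera called that list and no other. That simulation drew genes independently, so it does not show how often camera calls lists falsely among correlated genes; other divisions of the real arrays gave a median of 6 lists. For 8 cell type marker lists, the mean log2 value of the members on each array was compared with an exact two-sided permutation test over the 252 ways of dividing 10 arrays, whose smallest p is 0.00794. The same test was used for Sfrp5 and for the ratios of the 3 prime to the 5 prime control probesets of GAPDH and beta-actin, which rise with degraded RNA.

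The named genes are Sfrp5, which the series title names; the 10 genes in each direction with the lowest p, since no probeset passed the threshold; up to 4 members of each described list with the lowest p; and the hormone genes. A gene with several probesets is named from the brightest. Provisional symbols were passed over. Amy2a3, Emp1, and list members beyond the first 4 were named after their values were seen. The grouping, tests, lists and naming rule were set before the data were examined. The alternatives tried were other pseudocounts and filters, quantile normalization, median centring, limma's trended and robust variance, array weights, the replicate number as a block, the acinar index or the GAPDH ratio as a covariate, leaving out probesets open to cross-hybridisation, the mean of a gene's probesets, and leaving out each array. Plots were drawn with matplotlib 3.10.9. For arrays, the number of arrays limits the precision.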

Results

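Gene expression was measured in pancreatic islets, the hormone-secreting cell clusters of the pancreas, from male Wistar rats aged 7 weeks that ate standard chow or a cafeteria diet for 10 days. Fat supplied 8% of the calories of the chow and 66% of those of the cafeteria diet. Each group held 5 arrays of independent samples. Median signals ran from 150.8 to 173.2 across the 10 arrays, and pairs of arrays correlated with r between 0.9552 and 0.9819 across probesets. The comparison asks how islet gene expression differs after a short spell of high-fat feeding, and what happens to Sfrp5, a secreted inhibitor of Wnt signalling that the series title describes as reduced in obesity.

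Sfrp5 was lower in the cafeteria group, at a signal of 94.8 ± 59.0 (SD, n = 5) against 192.2 ± 67.4 (SD, n = 5) in the standard group. The groups follow the titles of the arrays; the diet characteristic of each sample states the opposite diet, and with it every direction given here would turn. The log2 difference was −1.06 with an SE of 0.365, a 2.08-fold lower level, with a 95% confidence interval from −1.86 to −0.25. An exact two-sided permutation test of this gene alone gave p = 0.0317, and limma's p adjusted over all probesets was 0.414, so Sfrp5 did not pass genome-wide. The gene was taken from the title of this series and may have been picked from these same arrays. If so, the permutation p is not an independent test. The groups overlapped: the cafeteria arrays ran from 35.8 to 177.8 and the standard arrays from 137.9 to 304.3. Sfrp5 was dim, with a mean log2 value at percentile 45.4 of the non-control probesets, not far above the filter at the 40th. Cafeteria replicates 3 and 5 read 35.8 and 39.6, and without detection calls it is not known whether these lie above background. Leaving out any standard array, cafeteria replicate 3 or cafeteria replicate 5 took the exact permutation p above the threshold, up to 0.0952 without standard replicate 1, while the difference stayed between −1.31 and −0.82.

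**Figure D1:**
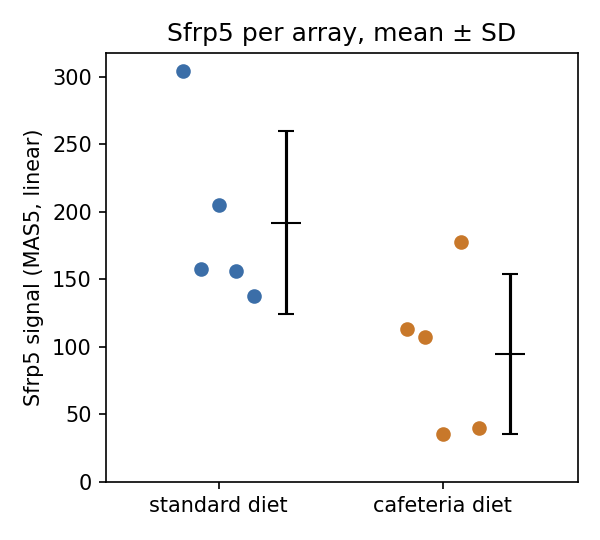
Sfrp5 signal (linear MAS5 scale, vertical axis) on each array of the 2 diet groups (points), with the group mean and SD at the right of each group. The cafeteria arrays lie between 35.8 and 177.8 and the standard arrays between 137.9 and 304.3.

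The list of Wnt ligands, receptors and inhibitors, which includes Sfrp5, did not pass the test. Of 18 measured members, 11 were lower and 7 higher in the cafeteria group, with a mean log2 difference of −0.13 (camera adjusted p = 0.0566; adjusted p = 0.496 with an estimated correlation). Without Sfrp5, left out after seeing the data, 10 of 17 were lower and the mean was −0.077 (camera adjusted p = 0.126). The ligands Wnt6 (−0.56, SE 0.155) and Wnt4 (−0.27, SE 0.078) and the receptor Fzd8 (−0.21, SE 0.075) were, with Sfrp5, the members of lowest p, and none passed adjustment over the list alone (lowest 0.0513). Without the filter on low signals the list mean turned to 0.061 (adjusted p = 0.81). The list passed with quantile normalization (adjusted p = 0.0309) and with the mean of a gene's probesets (0.0132). It also passed without standard replicate 4 (0.00337) or cafeteria replicate 1 (0.0172), 2 (0.0295), 3 (0.0435) or 4 (0.0457). Without standard replicate 3 or 5 its mean shrank to −0.075 or −0.080, and without standard replicate 1 to −0.085. Among 11 feedback and target genes of the pathway, 8 were lower and 3 higher. Lef1 differed by −0.47 (SE 0.298), Tcf7l2 by −0.43 (SE 0.226), Znrf3 by −0.26 (SE 0.174) and Axin2, a standard readout of β-catenin activity, by −0.054. The list did not pass the test (mean −0.25, camera adjusted p = 0.262), which does not show that it was unchanged. Its most negative member was Tcf7 (−1.62, SE 0.695), which lymphocytes also express.

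No single probeset passed the adjusted threshold. With limma, 0 of 18625 probesets had an adjusted p under 0.05 (lowest 0.172, a probeset of Emp1 at 0.67, SE 0.087, whose brightest probeset was at 0.069), while 1941 (10.4%) had an unadjusted p under 0.05 against 931 expected by chance, 1026 of them higher and 915 lower in the cafeteria group. Taking the brightest probeset of each gene, the genes with the lowest p that were higher were Asb9 (log2 difference 0.91, SE 0.161), Ros1 (0.47), Mlec (0.48), Cavin3 (0.46), Bud23 (0.42), Amigo3 (0.71), the calcium release channel gene Ryr3 (0.59), the clock gene Per2 (0.71, SE 0.155), Mlxipl (0.37, SE 0.082), which encodes the glucose-responsive transcription factor ChREBP, and the tight junction gene Cldn7 (0.65). Those that were lower were Carmil2 (−0.56), Rnf217 (−0.37), Clca2 (−0.56), Mmd (−0.46), Prps2 (−0.46), Runx1t1 (−0.63), Heca (−0.36), Ch25h (−0.61), which encodes cholesterol 25-hydroxylase, Fbxl17l1 (−0.48) and Sorcs2 (−0.38). Each of these 20 genes had an adjusted p of 0.398. The signal of Asb9 was 305.8 ± 57.1 (SD, n = 5) in the standard group and 591.2 ± 123.2 (SD, n = 5) in the cafeteria group, and that of Per2 was 647.3 ± 156.8 and 1048.8 ± 126.4.

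By camera, 7 of 25 gene lists shifted, 4 higher and 3 lower in the cafeteria group. Divisions of the same arrays other than by diet gave a median of 6 such lists, and 0 of the 7 passed with an estimated correlation (lowest adjusted p = 0.496 with an estimated correlation). The list with the lowest p was the cell cycle, with 59 of 68 measured members higher and a mean log2 difference of 0.21 (camera adjusted p = 2.06e-08; adjusted p = 0.496 with an estimated correlation). Examples are Nusap1 (0.60, SE 0.161) and Cenpf (0.53, SE 0.169), which act in mitosis, and Tyms (0.40, SE 0.139), which makes thymidylate for DNA synthesis; 14 members were higher and 1 lower at an unadjusted p under 0.05, and 0 passed over the list alone (lowest 0.214). The mean log2 value of the list per array was 8.62 in cafeteria replicate 5, 8.07 to 8.19 in 3 other cafeteria arrays, 7.91 in cafeteria replicate 4, and 7.96 to 8.02 in the standard arrays (exact permutation p = 0.0794). Without cafeteria replicate 5 the mean difference was 0.099 (adjusted p = 0.000227), and with the GAPDH 3 prime to 5 prime ratio as a covariate it was 0.369 (adjusted p = 1.44e-13).

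Cholesterol synthesis genes were higher in the cafeteria group. Of 22 measured members 18 were higher, 9 of them at an unadjusted p under 0.05, with a mean log2 difference of 0.15 (camera adjusted p = 5.27e-05; adjusted p = 0.496 with an estimated correlation). They included Pmvk (0.29, SE 0.079), Fdps (0.32, SE 0.090), Sqle (0.31, SE 0.095) and Mvd (0.31, SE 0.104), which catalyse successive parts of the route from mevalonate to sterols; 0 passed over the list alone (lowest 0.0517). The array means separated the groups fully, at 9.59 to 9.80 in the cafeteria arrays and 9.49 to 9.57 in the standard arrays. The exact permutation p was 0.00794, the smallest possible, and 0.198 after adjustment over the 25 lists, so a single list could not pass this test on its own.

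Genes of oxidative phosphorylation and of the unfolded protein response were also higher. For oxidative phosphorylation, 58 of 68 members were higher, by a mean of 0.089 (camera adjusted p = 8.92e-05; adjusted p = 0.57 with an estimated correlation), led by the ATP synthase subunit genes Atp5me (0.42, SE 0.143) and Atp5po (0.27, SE 0.105). This call rested on cafeteria replicate 5, without which the mean was 0.029 (adjusted p = 0.181), and with array weights it was 0.056 (adjusted p = 0.00787). For the unfolded protein response, 29 of 38 members were higher, by a mean of 0.087 (camera adjusted p = 0.000743; adjusted p = 0.496 with an estimated correlation), among them the endoplasmic reticulum proteins Creld2 (0.39, SE 0.116), Hsp90b1 (0.28, SE 0.101) and Manf (0.27, SE 0.098). Atf3, a stress-induced transcription factor that also belongs to the immediate early list, went the other way (−0.59, SE 0.218). The mean of this list was 0.046 without cafeteria replicate 5 (adjusted p = 0.00386) and 0.057 with quantile normalization (adjusted p = 0.00377).

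**Figure D2:**
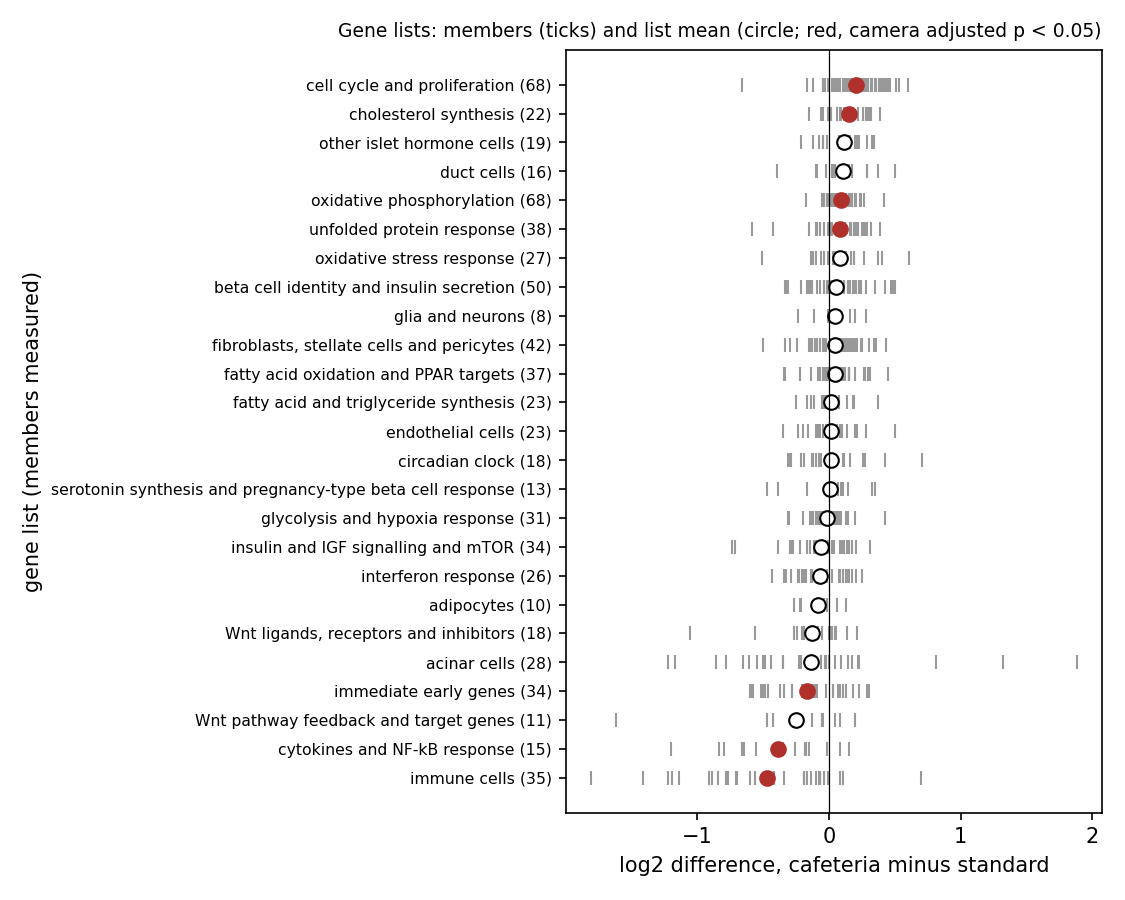
Log2 differences (cafeteria minus standard, horizontal axis) of the measured members of 25 gene lists (ticks) and each list's mean (circles, filled red where the camera adjusted p is under 0.05). The list means run from −0.474 for immune cells to 0.206 for the cell cycle, and the acinar members reach from −1.23 to 1.89.

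Immune cell, cytokine and immediate early genes were lower in the cafeteria group. Of 35 immune cell markers 32 were lower, by a mean log2 difference of −0.47 (camera adjusted p = 5.27e-05; adjusted p = 0.496 with an estimated correlation), among them Itgb2 (−0.77, SE 0.257), Cxcr4 (−0.85, SE 0.326), the B cell gene Ms4a1 (−1.81, SE 0.776) and the MHC class II gene RT1-Da (−0.78, SE 0.361). Of 15 cytokine and NF-κB response genes 13 were lower, by a mean of −0.39 (camera adjusted p = 0.0027; adjusted p = 0.496 with an estimated correlation), with Tnfaip3 (−0.65, SE 0.220) and Ccl4 (−0.66, SE 0.249) as examples; the probesets of Il1r1 (−0.35 from the brightest) disagreed in direction. Of 34 immediate early genes 23 were lower, by a mean of −0.17 (camera adjusted p = 0.00302; adjusted p = 0.496 with an estimated correlation). Jun (−0.49, SE 0.108), Ier5 (−0.46, SE 0.119) and Zfp36 (−0.52, SE 0.140) passed the test adjusted over the list alone (lowest 0.0288), with 0 members past the test over all probesets, and Fos differed by −0.58 (SE 0.186).

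An RNA quality measure differed along with these 3 lists. The ratio of 3 prime to 5 prime GAPDH control signal averaged 1.16 in the standard group and 1.01 in the cafeteria group, a log2 difference of −0.205 (exact permutation p = 0.0238, adjusted p = 0.0476), while the beta-actin ratio was 2.81 and 2.64 (exact permutation p = 0.405). The GAPDH difference missed the threshold without standard replicate 1, 3, 4 or 5 (−0.174 without replicate 1, exact permutation p = 0.0635). With the GAPDH ratio as a covariate the immune mean was −0.085 (adjusted p = 0.81), the cytokine mean −0.159 (adjusted p = 0.567) and the immediate early mean 0.045 (adjusted p = 0.615), so none of the 3 calls held. With the immune index as a covariate, chosen after seeing the data, the cytokine and immediate early means were −0.140 and −0.076 (adjusted p = 0.302 for both). Without standard replicate 3 the immediate early mean was −0.102 (adjusted p = 0.0766), and with the filter at the 70th percentile the cytokine mean was −0.202 (adjusted p = 0.141).

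**Figure D3:**
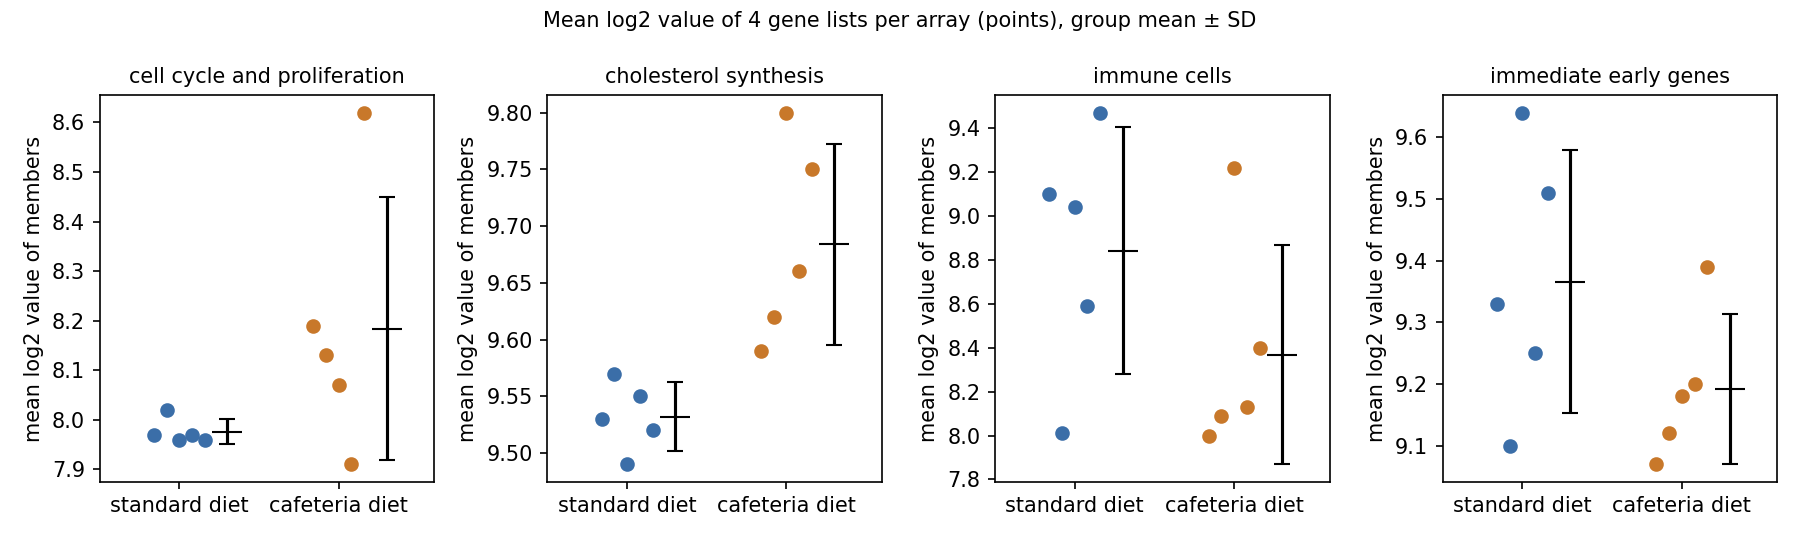
Mean log2 value of the members of 4 gene lists (vertical axes) on each array of the 2 diet groups (points), with group mean and SD. The groups separate fully for cholesterol synthesis (9.59 to 9.80 against 9.49 to 9.57), cafeteria replicate 5 stands highest for the cell cycle at 8.62, and the immune panel shows cafeteria replicate 3 at 9.22 and standard replicate 2 at 8.01, each away from most of its group.

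No hormone gene and neither islet gene list passed the test. Ins1 (0.16, SE 0.146), Ins2 (0.21, SE 0.147), Gcg (0.23, SE 0.098), Sst (0.21, SE 0.095) and Ppy (0.20, SE 0.116) were each higher without passing (adjusted p from 0.46 to 0.71). These genes lie near the top of the array's range, where saturation can compress a difference: Gcg had a signal of 30404.2 ± 3329.1 (SD, n = 5) in the standard group, against highest signals per array of 36432.6 to 49015.8. The list of other islet hormone cells had 12 of 19 members higher (mean 0.11, camera adjusted p = 0.0522). It passed with median centring (adjusted p = 0.032) and with the trended and robust variance (0.0439). It also passed without standard replicate 1 (0.0159) or 4 (0.00503) or cafeteria replicate 3 (0.0484), 4 (0.0457) or 5 (0.00473). Without standard replicate 5, however, the mean was 0.010 (adjusted p = 0.698), and without cafeteria replicate 1 it was 0.065 (0.243). Of 50 genes of β-cell identity and insulin secretion 29 were higher and 21 lower (mean 0.051, camera adjusted p = 0.139), with the incretin receptor gene Gipr at 0.43 (SE 0.10), Chga at 0.28 (SE 0.110), and the transcription factor genes Pdx1 at −0.21 (SE 0.080) and Sox4 at −0.33 (SE 0.103), whose probesets disagreed in direction.

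Of the markers of other cell types that hand-picked islets can carry, the immune list passed camera as given above. By the exact permutation test of the means per array, 0 of 8 marker indices passed (adjusted p at least 0.476). With a smallest possible p of 0.00794, a single index could not pass adjustment over 8 on its own. The lowest exact permutation p before adjustment was 0.119, for the duct index. The acinar index, for the digestive enzyme cells around the islets, differed by −0.13 (exact permutation p = 0.722), the immune index by −0.47 (exact permutation p = 0.198), and the red blood cell index, of 4 members, by 0.15 (exact permutation p = 0.127). Duct, adipocyte and glial indices differed by 0.11, −0.086 and 0.048, fibroblast and endothelial indices by 0.044 and 0.018. The acinar list passed camera without cafeteria replicate 4 (mean −0.385, adjusted p = 0.00234) or 5 (−0.349, adjusted p = 0.00627), not with all arrays (adjusted p = 0.262). Its mean turned to 0.078 without cafeteria replicate 3 and 0.023 without standard replicate 5. Within it, single enzymes differed in opposite directions. The trypsinogen genes Prss3 (1.89, SE 0.490) and Prss2 (1.32, SE 0.407) were higher and the phospholipase gene Pla2g1b (−1.23, SE 0.379), the elastase gene Cela1 (−0.78, SE 0.267) and the amylase gene Amy2a3 (−1.17, SE 0.412) lower, none past adjustment (adjusted p 0.398 to 0.418). Prss3 and Prss2 were dim, with mean signals of 57.1 and 86.7 in the standard group. The brighter trypsinogen gene Prss1 (2649.6 there) differed by −0.12 (SE 0.441), so trypsinogen genes did not rise as a set. With the acinar index as a covariate Amy2a3 was the sole probeset to pass, at −0.99 (SE 0.097, adjusted p = 0.0213). Amy2a3 is itself a member of that index, so the covariate contains the gene it adjusts. This p-value does not allow for that.

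**Figure D4:**
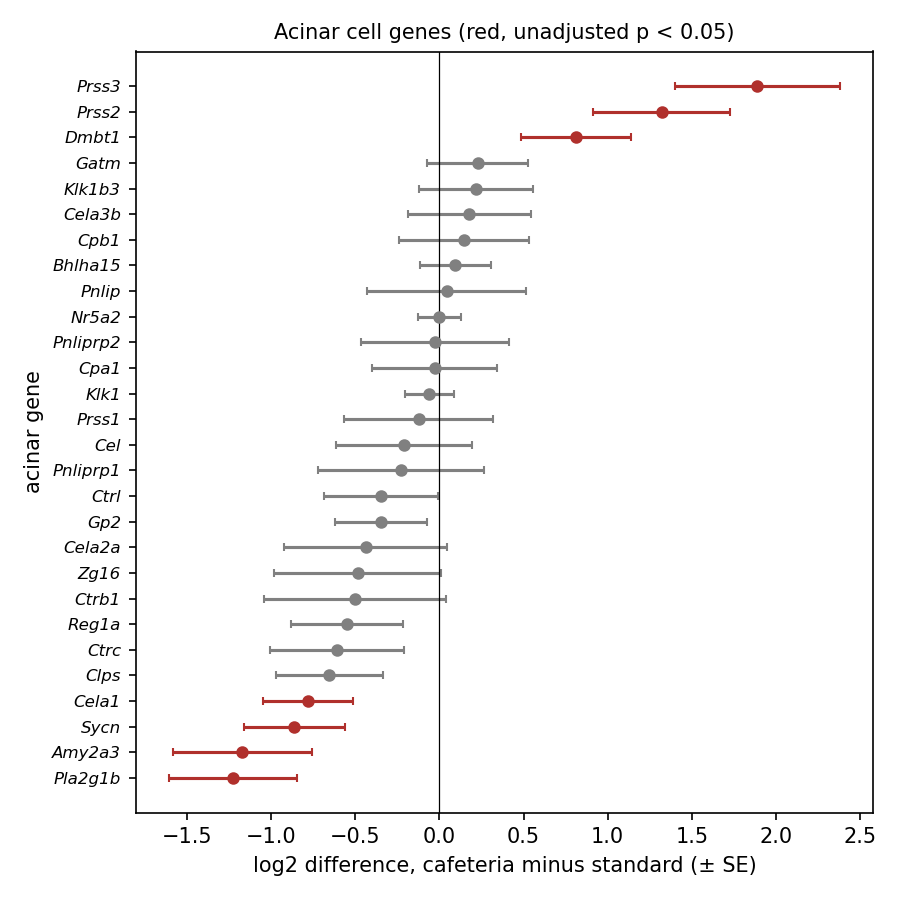
Log2 differences (cafeteria minus standard, horizontal axis) with SE for the 28 acinar cell genes measured (vertical axis), red where the unadjusted p is under 0.05. The 7 red genes are 3 higher, up to Prss3 at 1.89, and 4 lower, down to Pla2g1b at −1.23.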

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

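Of 296 sets of 5 arrays tested (148 named genes, list means and quality ratios in each group), 20 held an array far from the other 4 by Dixon's criterion, against 14.8 expected by chance, which marks about 1 set in 20. All values are log2. Cafeteria replicate 5 accounted for 6 of them. It was highest for the endoplasmic reticulum chaperone Hsp90b1 at 14.78 (others 14.32 to 14.36), the granule protein Chgb at 14.36 (others 13.52 to 13.70), Acsl5 at 11.17 (others 10.70 to 10.83), Mgp at 14.18 (others 13.70 to 13.81) and the mean of the serotonin and pregnancy-type list at 10.58 (others 10.35 to 10.40), and lowest for Acsl1 at 9.60 (others 9.90 to 9.98).

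In the other cafeteria arrays, Aldoc was lowest in replicate 3 at 6.66 and the cytokine list mean was highest there at 8.71; Cldn7 was lowest in replicate 4 at 8.96; Ros1 was lowest in replicate 2 at 9.54; and the fatty acid and triglyceride synthesis mean was lowest in replicate 1 at 10.06. Among standard arrays, replicate 2 was highest for Ros1 at 9.48, Mvd at 7.68 and the cell cycle mean at 8.02. Standard replicate 3 was lowest for Ddit4 at 9.29, Manf at 12.76 and Ndufs3 at 10.30. In standard replicate 4 Pfkfb4 was highest at 8.26 and the duct mean lowest at 9.33, and in standard replicate 5 Gcg was lowest at 14.59.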

How the results depend on the processing

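There were 27 other settings, 10 of which left out an array, and 23 of them gave values for single genes. Of the values for named genes, 2823 kept both their direction and their side of the threshold, 3 turned and 1 gained a call. No named gene passed in the main fit, so keeping its side of the threshold says little. The count of probesets past the threshold, 0 with limma, was 1 with the acinar index as a covariate (Amy2a3, itself a member of that index). It ran from 0 to 1 when an array was left out (1 without standard replicate 2, Emp1 at 0.73, adjusted p = 0.0386). The count of lists, 7, was 0 with an estimated correlation and ranged from 6 without standard replicate 3 to 11 without cafeteria replicate 4. Chosen after seeing the data, the immune index as a covariate left 4 lists, leaving Sfrp5 out of the Wnt list left 7, and an exact permutation of the array means in place of camera left 0 (lowest adjusted p = 0.198). With the GAPDH ratio as a covariate 5 lists passed, 4 of the 7 and the fibroblast list (mean 0.146, adjusted p = 0.0153). The cytokine list also missed the threshold with the filter at the 70th percentile (mean −0.202, adjusted p = 0.141). Calls gained by the Wnt, islet hormone, acinar, duct, fibroblast and interferon lists stand beside those lists. The cause of these changes was not tested. Leaving out an array, Sfrp5 by exact permutation ranged from −1.307 to −0.822 (p up to 0.0952) and the GAPDH ratio from −0.257 to −0.174, both past the threshold only in some runs. The replicate numbers were not taken to pair the arrays. Same-numbered arrays correlated at 0, 0.30, 0.25, 0 and 0.14 (median of other pairs across the groups −0.02), and 2 of the 5 standard arrays were closest to their own number. The log2 beta-actin ratio was lowest in replicate 2 (1.325 standard, 1.164 cafeteria) and highest in replicate 3 (1.677, 1.585) of both groups. A batch shared by number is therefore not excluded. With the replicate block 0 probesets and 7 lists passed, while the exact permutation tests were run without pairs.

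Directions that turned all belonged to results that were not called, except the immediate early list. With the GAPDH ratio as a covariate, the immediate early mean turned to 0.045, the acinar mean to 0.111, the clock mean to −0.006, Lef1 to 0.221 and Prph to −0.088. The serotonin list turned to −0.022 with array weights, −0.002 with median centring and −0.006 with quantile normalization. The filter at the 70th percentile turned the endothelial mean to −0.008 and the interferon mean to 0.060, no filter turned the Wnt list to 0.061, the immune covariate the clock mean to −0.034, and the probeset mean the glycolysis mean to 0.013. Leaving out an array, values on both sides of 0 were found for Prph (−0.026 to 0.303), the acinar list and index (−0.385 to 0.078), the clock list (−0.032 to 0.058), the endothelial list and index (−0.021 to 0.063), the fibroblast list and index (−0.004 to 0.098), the glycolysis list (−0.030 to 0.018) and the serotonin list (−0.031 to 0.035). Dim genes are limited most, since a fold change on the log2(value + 14.15) scale is drawn toward 0 there.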

Other observations

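Lipid and clock genes carried single differences in lists that did not shift as a whole. Per2 and Mlxipl were each the only member to rise by the test adjusted over its list alone, Per2 (0.71, adjusted p over the list 0.0143) among 18 clock genes and Mlxipl (0.37, adjusted p over the list 0.0184) among 23 genes of fatty acid and triglyceride synthesis. Adjustment within a list does not allow for the 25 lists, and by limma over all probesets both had an adjusted p of 0.398. The clock list had a median of −0.068, a mean of 0.015 and a camera adjusted p of 0.989, with Cry2 at 0.28 and Npas2 at −0.32. The lipid synthesis list had a mean of 0.019 (camera adjusted p = 0.51). Of 37 genes of fatty acid oxidation and PPAR targets 24 were higher, by a mean of 0.043 (camera adjusted p = 0.139), with the mitochondrial dehydrogenase Acadvl at 0.27 (SE 0.081) and Acsl5 at 0.30 (SE 0.096), and the carnitine transporter Slc22a5 at −0.34 (SE 0.110). Their array mean was higher in the cafeteria group with an exact permutation p of 0.0238, or 0.298 adjusted over 25 lists.

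Growth signalling and stress lists did not pass. In the insulin, IGF and mTOR list 20 of 34 members were lower (mean −0.061, camera adjusted p = 0.685), with Igfbp3 at −0.71 (SE 0.257), Foxo3 at −0.29 (SE 0.109) and Pik3r1 at −0.74 (SE 0.315). The serotonin and pregnancy-type list had a mean of 0.010 (camera adjusted p = 0.297) with Fkbp11 at 0.33 and Chgb at 0.35, and the oxidative stress list a mean of 0.083 (camera adjusted p = 0.139) with Mgst1 at −0.51 and Mt2A at 0.61. Interferon genes had a mean of −0.069 (camera adjusted p = 0.278, but −0.127 and 0.0484 without cafeteria replicate 3, and −0.022 and 0.893 without cafeteria replicate 1), led by Psmb9 at −0.33, and glycolysis and hypoxia genes −0.012 (camera adjusted p = 0.91), with Pfkfb4 at 0.42. Of the cell type lists, duct (mean 0.106, led by Krt18 at 0.38), fibroblast (0.044, Thy1 at 0.43), endothelial (mean 0.018 with a median of −0.001, Rgcc at 0.50), adipocyte (−0.086) and glial genes (0.048, Uchl1 at 0.20) had camera adjusted p-values of 0.111, 0.206, 0.91, 0.262 and 0.562. The duct list passed with the filter at the 70th percentile (mean 0.145, adjusted p = 0.0335) and without cafeteria replicate 4 (0.157, adjusted p = 0.0305), but its mean was 0.067 without cafeteria replicate 1 (adjusted p = 0.252). The fibroblast list passed without standard replicate 5 (0.098, adjusted p = 0.0213) and with the GAPDH ratio as a covariate (0.146, adjusted p = 0.0153), but its mean was 0.013 without standard replicate 4, 0.022 without standard replicate 2 and −0.004 without cafeteria replicate 5.

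The tests below were chosen after the results were seen, except the counts over other splits of the arrays. Of the 126 distinct splits of the 10 arrays into groups of 5, 100 were drawn with the real one included. The diets gave 1941 probesets at an unadjusted p under 0.05, and 2 of the 100 splits gave at least as many (highest other 2498). The 2 include the real split, so chance is unlikely for that count but cannot be excluded. For probesets past the adjusted threshold all 100 give at least the real 0 by construction (highest other 39), so that count cannot be tested this way. For lists 34 of 100 gave at least 7 (highest other 11, median 6), so chance cannot be excluded, which holds for the list calls by camera as a whole. The split with 39 probesets set standard replicates 1, 3, 4 and 5 with cafeteria replicate 3 against the rest. Those 5 arrays had immune marker means of 8.59 to 9.47 and the other 5 of 8.00 to 8.40. This split was picked as the highest and keeps most arrays of each diet together. It therefore does not separate diet from another structure of the samples, which was not tested.

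Acinar enzymes moved apart between the diets, with 7 of 28 members at an unadjusted p under 0.05, against 2.9 expected at the 10.4% found over all tested probesets; the members are correlated (0.575). A different amount of acinar tissue would shift the members together, yet their differences had an SD of 0.667, wider than in every other split of the arrays (highest other 0.574, median 0.305, exact share 0.00794, the smallest possible), which argues against it as the whole cause. Draws of 28 tested probesets of matching signal gave as large an SD in 0 of 10000 draws (highest 0.477, share 1e-04, the smallest possible). Signal level alone therefore did not give this SD. The draws did not match how much acinar members vary between arrays, and a split other than by diet also exceeded them (0.574). They cannot tell a diet difference from noise in acinar members. Probes shared between trypsinogens stay open, as does noise in single members, since neither was tested. A candidate explanation is that acinar cells left on the islets responded to a diet with more of its calories as fat, since amylase is known to follow dietary carbohydrate. Genes of lipid digestion showed no matching rise: Pnlip differed by 0.043 (SE 0.471), Pnliprp1 by −0.227, Pnliprp2 by −0.024, Cel by −0.211, Clps by −0.654 and Pla2g1b by −1.227. No test here separates this explanation from other effects of the diet.

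Immune genes were lower in 32 of 35 markers. Immune tissue picked unevenly with the islets stays open, since the mean of the list spanned 1.47 within the standard group and 1.23 within the cafeteria group, more than the difference of −0.474 between them (exact permutation p = 0.198). RNA quality cannot be told apart from it: with the GAPDH ratio as a covariate the list mean went from −0.474 to −0.085 (adjusted p = 0.81), and that ratio itself differed between the diets. The B cell gene Ms4a1 differed by −1.81 and the macrophage genes C1qa and Cd68 by −0.14 and −0.07, but whether kinds of immune cell differ was not tested. An effect of diet on immune cells in or near the islets also stays open, as untested.

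Cell cycle genes were higher in 59 of 68 members and the list passed camera at the preset correlation, but their mean per array gave an exact permutation p of 0.0794, so a chance difference between these 10 arrays stays open. Cafeteria replicate 5 alone stays open too, since without it the difference of the array means was 0.0969 with an exact permutation p of 0.151, and the other cafeteria arrays (7.91 to 8.19) lay on both sides of the standard ones (7.96 to 8.02). Differing amounts of immune and acinar tissue were weighed through their indices. By its slope within the groups, the immune index accounted for 0.0119 of the difference of 0.206 in array means (95% interval −0.138 to 0.162). The acinar index accounted for −0.00767 (up to 0.0325). Without cafeteria replicate 5 both bounds (0.0825 and 0.0569) also lay under the difference of 0.0969 there. These bounds take the differences between the groups as free of error. The acinar index hardly differed between the diets (−0.133, exact permutation p = 0.722), so its part was bound to be small. The immune index follows the amount of immune cells, not how many divide, so dividing immune cells stay open. A diet effect on dividing islet cells stays a hypothesis, and which cells were dividing was not tested.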
